A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

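The samples are genomic run-on hybridisations of 6 Saccharomyces cerevisiae strains, with 3 run-on arrays per strain on 7 membranes numbered 12 to 18. Per the labels' protocols, permeabilised cells were incubated with 33P-labelled UTP, and per the series' design text the labelled RNA was hybridised to home-made membranes carrying entire open reading frames, with a genomic DNA hybridisation of the same membranes for normalisation and a later normalisation by median absolute deviation (MAD). The deposited files are spot tables from image quantification, before that normalisation. Of 36 files, 18 hold run-on arrays and 18 hold genomic DNA, and the latter are copies of 7 hybridisations, 1 per membrane. The imaging program is not given in the sources used here. Per the file headers, the density column is an intensity per area. The deposited background-subtracted intensity column holds that density less its background, set to 0 where the result is negative, as checked on the values. The deposited S/N column is a score of signal over background. No scaling between membranes is visible in the deposited intensities.

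Strain was taken from each sample's title. The source label of the cln3 deletion sample describes wild-type cells in medium with potassium chloride, while its title, description and strain label name the cln3 deletion. The title was followed, and the conflict stays open wherever a direction is given for that strain. Run-on number and membrane are known only from the deposited names of the arrays, and replicate numbers in the text are run-on numbers. No 2 run-on arrays held identical values, and r between run-on arrays lay from 0.868 to 0.983 on log2 signal.

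Each run-on intensity was divided by the genomic DNA intensity of its membrane, and the log2 ratio was centred on the array's median and scaled to a common MAD (0.888 to 1.072 before scaling). A spot entered where genomic DNA was above 0 on all 7 membranes and run-on signal above 0 on all 3 arrays of at least 1 strain. This left out 207 of 6144 spots, 191 of them for genomic DNA, and signals of 0 among the rest were treated as missing (240 values, 0.22%). All 18 arrays were fitted in 1 linear model of strain means (limma 3.58.1 in R 4.3.3, lmFit and eBayes), and a spot was called at a Benjamini-Hochberg adjusted p under 0.05. A trend on log2 ploidy was fitted over the 12 wild-type arrays. Where a spot had S/N under 2 on all 3 arrays of a strain, only a bound is given ("at least N-fold"). It is the mean of the other strain against the mean, per array, of the higher of the spot's own signal and the lowest signal among spots with S/N of at least 2. The S/N of 2 was set after the data were seen. The overall level was compared by exact permutation tests on array medians before centring.

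On simulated data for tetraploid against haploid (5845 spots, 100 changed per size), the fit recovered 58% of changes of 1 log2 unit and 94% of changes of 2 log2 units, with 3.8% of calls false, and made 0 calls between the simulated deletion strains, which did not differ. The simulated noise was independent between arrays, so these rates leave out deviations shared by run-on number or membrane. In the real fit the median standard error of a log2 difference between 2 strains was 0.25.

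Named spots follow a rule fixed before the data were examined: the largest changes in each direction among called spots whose 3 values lie outside the range of the other strain's 3 values, or the smallest p where fewer than 5 passed. The rule allowed up to 6 per direction. Because the files pair no spot with a gene, at most 2 per direction are given, a reduction made after the data were seen, and the planned tests of gene lists, of CLN3 and WHI5 themselves and of marker genes were not run. The tables of gene names at hand hold no array positions. Whether the labels name the right strain was therefore not checked on the deleted genes. Spots outside the rule are said to be so.

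Arrays with the same run-on number were tested for shared deviations from their strain means. In whi5 deletion, diploid and tetraploid against haploid all 3 correlations exceeded 0.1 (0.43, 0.19 and 0.31, then 0.40, 0.13 and 0.25, then 0.31, 0.20 and 0.11), and run-on number was taken to pair these arrays. In the other comparisons at least 1 correlation was lower. Between strains, the 15 pairs of run-on 1 arrays correlated in these deviations with a median of 0.35 and pairs on the same membrane with a median of 0.13. Membrane, as a batch that holds several strains, was fitted as a fixed block (statmod 1.5.0 for the random block, consensus correlation 0.28). Alternatives set before the data were examined were other scalings (no MAD scaling, quantile, cyclic loess), no genomic DNA division, density without background subtraction, other filters on dim spots, run-on number or membrane as a block, only the strains compared, an intensity trend in the variance with robust moderation, other forms of the trend, and leaving out each array. Alternatives added later were floored signals, both blocks together, leaving out the 6 run-on 1 arrays, the mean of the polyploids, contrasts sharing no run-on array, and the same contrasts from arrays that share no membrane.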

Results

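Nascent transcription was measured in 6 strains of budding yeast that differ in cell volume, growing exponentially. The growth labels give rich medium (YPD), but for the cln3 deletion strain the source label also names potassium chloride, and its medium stays open. A wild-type haploid (BY4741), a deletion of CLN3, which encodes a G1 cyclin that promotes entry into the cell cycle, and a deletion of WHI5, which encodes a repressor of the G1/S transcription programme, were set beside wild-type diploid, triploid and tetraploid strains. In genomic run-on, cells are permeabilised with the detergent sarkosyl and engaged RNA polymerases extend their transcripts with radioactive UTP, so that the label on an array spot follows the density of transcribing polymerase over that open reading frame. Each strain had 3 run-on arrays, 18 in all, on home-made membranes that carry whole open reading frames. Each array held 6144 spots. The files name a spot by its place on the membrane (block row, block column and position in the block) and do not pair it with a gene. Spots are therefore given by place, and pathways or gene groups were not tested. Median run-on signal ranged from 38.99 in haploid replicate 1 to 166.4 in triploid replicate 3, and between 73.5% and 83.7% of spots on an array had a signal-to-noise ratio (S/N) of at least 2. Of the 6144 spots, 5937 entered the tests. The number of arrays, 3 per strain, limits the precision. The labels do not say that the 3 arrays came from separate cultures, so p-values measure only the spread between these arrays.

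The first question was whether the run-on signal as a whole followed cell volume. The median log2 ratio of run-on to genomic DNA signal was 0.82 ± 0.27 (SD, n = 3) in the wild-type haploid and 1.20 ± 0.71 (SD, n = 3) in the triploid. It was 0.53 ± 0.49 (SD, n = 3) in the cln3 deletion strain. The difference from the haploid was -0.28 in the cln3 deletion, -0.07 in the whi5 deletion, 0.01 in the diploid, 0.38 in the triploid and 0.01 in the tetraploid. Two-sided exact permutation tests gave p = 0.5, 0.9, 1, 0.4 and 1 in that order, and 1 for each of the 5 after Benjamini-Hochberg adjustment. With 3 arrays against 3 the smallest p possible is 0.1, so no difference could have passed. The differences depended on single arrays and on genomic DNA: that of the triploid was -0.01 without triploid replicate 3, and that of the whi5 deletion was 0.38 without division by genomic DNA. Exposure time and the amount of labelled RNA put on each membrane are not given in the sources used here, so these levels are not transcription rates, and the tests below compare each spot with the rest of its own array.

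The cln3 deletion strain differed from the wild-type haploid at 43 of 5933 tested spots, 24 higher and 19 lower. The strain label was not checked on CLN3 itself, so these differences cannot be assigned to the deletion alone. The spot in row 16, column 19, position 11 was not above background on any of the 3 haploid arrays and rose at least 19-fold in the cln3 deletion (adjusted p = 3.9e-05). It was below an S/N of 2 on all 12 arrays of the other 4 strains as well, and its genomic DNA was below 2 on 2 membranes. At row 4, column 11, position 8, signal was likewise not above background in the haploid and rose at least 2.9-fold (adjusted p = 6.1e-05). Signal fell by 4.31 on the log2 scale (SE 0.58, adjusted p = 0.00094) at row 16, column 20, position 1, from 2.77 ± 0.28 to -1.54 ± 0.07 (SD, n = 3 each). At row 1, column 14, position 11 it fell at least 4.6-fold (adjusted p = 0.015), to a signal not above background. Its genomic DNA signal was below an S/N of 2 on 4 membranes, and its call was lost with membrane as a fixed block (adjusted p = 0.16), with only the 2 strains in the fit (adjusted p = 0.14) or without any of 4 arrays (adjusted p = 0.051, 0.062, 0.067 and 0.06 without haploid replicate 1, 2 or 3 or cln3 deletion replicate 3). These losses do not show a smaller change. All values and tests for spots come from limma, with Benjamini-Hochberg adjustment over the tested spots. The haploid and the cln3 deletion shared membranes 13 and 14. On these, 42 of 42 and 40 of 40 called spots with a value differed in the direction called, and with membrane as a fixed block 34 spots passed. The balance of rises and falls depended on the processing. It was 122 higher and 154 lower with both blocks, 20 and 27 without cln3 deletion replicate 1, 35 and 38 with membrane as a random block, 20 and 21 without MAD scaling, 25 and 26 with quantile normalisation and 18 and 19 with uncorrected density. It was even with cyclic loess (22 each), the upper 75% of signal (15 each) and run-on number as a block (38 each). These are the arrays the calls were made from. Single arrays weighed on the count, which was 27 without haploid replicate 1, 27 without replicate 2, 18 without replicate 3, 21 without cln3 deletion replicate 2 and 25 without replicate 3.

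**Figure D1:**
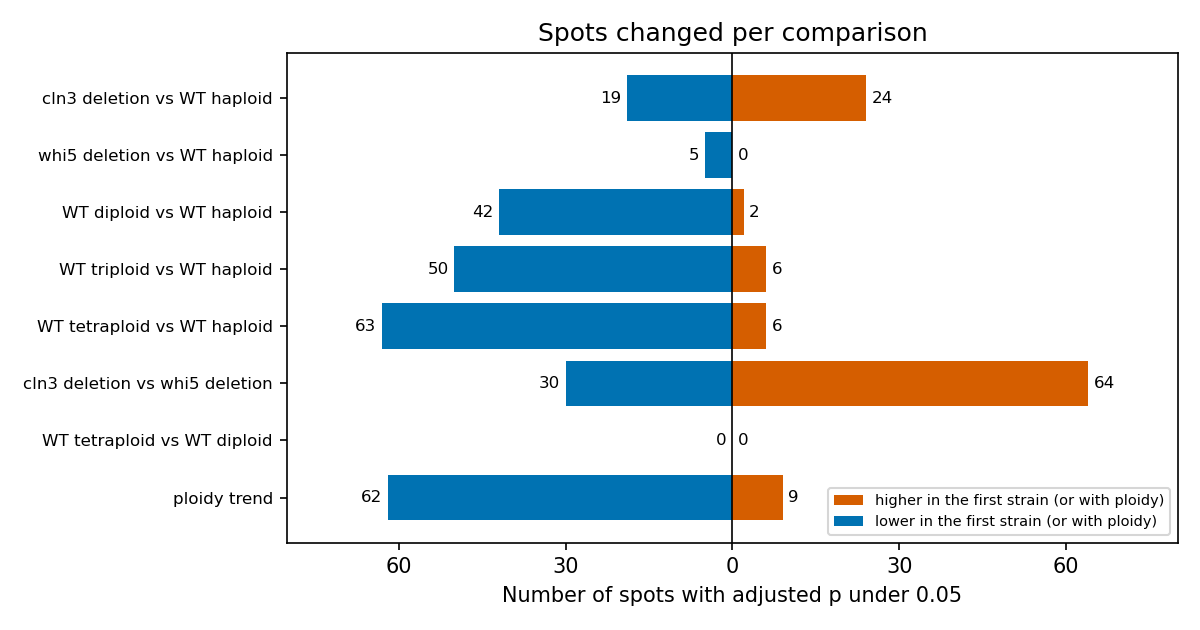
Number of spots with adjusted p under 0.05 (horizontal axis, counted from 0 to each side) for each comparison of 2 strains and for the trend over ploidy. Bars to the right count spots higher in the first strain named, or rising with ploidy, and bars to the left spots lower. Polyploid strains gave mostly lower spots, from 42 in the diploid to 63 in the tetraploid, and no spot was called between tetraploid and diploid.

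Few spots were called for the deletion of WHI5. Against the wild-type haploid 5 of 5933 tested spots fell and 0 rose, and 182 spots had an unadjusted p under 0.05 where 297 would be expected by chance. Such a deficit can come from p-values that are too large, so the few calls do not show that few spots changed. With run-on number and membrane both as blocks 8 spots passed, 4 higher and 4 lower. At row 5, column 2, position 7, a bright spot with an S/N of at least 187.82 on the arrays of both strains, signal fell by 1.40 on the log2 scale (SE 0.24, adjusted p = 0.043). The same spot fell by 1.27 in the diploid, 1.52 in the triploid and 1.41 in the tetraploid (adjusted p = 0.015, 0.0032 and 0.0063). In the cln3 deletion the log2 difference was -0.81 (SE 0.24, adjusted p = 0.23). The haploid thus lay above every other strain at this spot, and the fall was not particular to the whi5 deletion. At row 5, column 17, position 11, signal was not above background in the whi5 deletion, at least 1.3-fold lower than in the haploid (adjusted p = 0.0019), with genomic DNA below an S/N of 2 on 5 membranes. This call was lost with uncorrected density, membrane as a fixed block, only the 2 strains in the fit or floored signals (adjusted p = 0.42, 0.29, 0.21 and 1). With uncorrected density the change itself was smaller than in the main fit (log2 difference -0.83), whereas with only the 2 strains it was not. Run-on number paired the arrays of this comparison, and with it as a block 10 spots passed, all lower. The 2 strains shared no membrane, so within-membrane values do not exist, and with membrane as a fixed block 0 spots passed. The count was 3 without haploid replicate 1 or 3, or whi5 deletion replicate 1 or 2, and the call at row 5, column 2, position 7 was lost without any of haploid replicates 1, 2 and 3 or whi5 deletion replicates 1 and 2 (adjusted p = 0.086, 0.25, 0.19, 0.39 and 0.24). It was lost as well without MAD scaling (adjusted p = 0.055), with quantile normalisation (0.077), membrane as a fixed block (0.97), only the 2 strains (0.51), floored signals (0.065), both blocks (0.076) and without the run-on 1 arrays (0.38). The log2 difference stayed between -1.24 and -1.41 under these choices, except without haploid replicate 1, where the fall was larger. The lost calls thus do not show a smaller change.

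Set directly against each other, the 2 deletion strains, which move cell volume in opposite directions, differed at 94 of 5934 spots, 64 higher and 30 lower in the cln3 deletion. The spot in row 3, column 2, position 8 was at least 25-fold higher in the cln3 deletion (adjusted p = 0.00019) and not above background in the whi5 deletion. A further rise, of at least 3.7-fold, was at row 4, column 11, position 8 (adjusted p = 0.00019). Row 16, column 20, position 1 was lower, with a log2 difference of -4.45 (SE 0.58, adjusted p = 0.00041), since the whi5 deletion kept a level of 2.90 ± 0.64 (SD, n = 3). Row 1, column 14, position 11 was at least 2.6-fold lower (adjusted p = 0.022), with genomic DNA below an S/N of 2 on 5 membranes. Its call was lost with membrane as a fixed block (adjusted p = 0.31), only the 2 strains in the fit (0.15), floored signals (0.25) or both blocks (0.07). It was also lost without cln3 deletion replicate 2 or 3 or whi5 deletion replicate 1, 2 or 3 (adjusted p = 0.079, 0.073, 0.068, 0.054 and 0.11). The losses with membrane as a block or only the 2 strains do not show a smaller change. Row 3, column 2, position 8 had an S/N of at least 2 in the cln3 deletion alone. At the other spots named here the cln3 deletion was called against the haploid and the whi5 deletion was not. Membrane 15 held an array of each strain, and 93 of 93 called spots with a value differed there in the direction called, though the calls were made from these arrays. With membrane as a fixed block 21 spots passed. The count was 45 without cln3 deletion replicate 2, 47 without whi5 deletion replicate 2 and 62 without whi5 deletion replicate 3.

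Each polyploid differed from the haploid mainly by loss of signal. Of 44 changed spots in the diploid 42 fell, of 56 in the triploid 50 fell, and of 69 in the tetraploid 63 fell. At row 16, column 20, position 1 the log2 difference was -4.87, -4.95 and -5.09 in diploid, triploid and tetraploid (SE 0.58 each, adjusted p = 0.00022, 0.00015 and 0.00011). In the diploid, row 1, column 7, position 4 fell at least 3.4-fold (adjusted p = 2.1e-06). Its S/N was 0.07 or less on all 9 polyploid arrays, while the haploid stood at -1.05 ± 0.30, the cln3 deletion at -0.73 ± 0.33 and the whi5 deletion at -1.18 ± 0.22 (SD, n = 3 each). In the triploid, row 1, column 14, position 11 fell at least 5.4-fold (adjusted p = 0.013), with genomic DNA below an S/N of 2 on 4 membranes. The call was lost with membrane as a fixed block (adjusted p = 0.1) and without haploid replicate 2 or 3 or triploid replicate 2 (adjusted p = 0.061, 0.062 and 0.084), which does not show a smaller change. This spot was called lower in the diploid and tetraploid too (adjusted p = 0.038 and 0.00094), each with 2 arrays above 0. In the tetraploid, row 14, column 10, position 9 fell at least 17-fold (adjusted p = 0.0021), with genomic DNA below an S/N of 2 on 4 membranes. It was called lower in the diploid, triploid and cln3 deletion as well (adjusted p = 0.0046, 0.0018 and 0.0095). Among the few spots that rose, row 12, column 18, position 1 rose by 1.55, 1.42 and 1.65 on the log2 scale (SE 0.22 each, adjusted p = 0.0012, 0.0023 and 0.00057). Its genomic DNA was below an S/N of 2 on 3 or 4 of the membranes of each comparison. The S/N of the haploid arrays was 1.01 to 2.12 there, so the size of these rises rests on a level near background. With uncorrected density the rises were 0.90, 0.84 and 0.98 (adjusted p = 0.015, 0.022 and 0.006). Row 4, column 11, position 8 rose at least 1.7-fold, 2.8-fold and 2.5-fold (adjusted p = 0.00066, 9.5e-05 and 0.00011), and with signals floored its diploid call was lost (adjusted p = 0.24).

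Membrane and single arrays bore on these counts. Membrane 18 held only polyploid arrays, and membranes 14 and 15 only haploid or deletion arrays. Membrane was thus partly confounded with polyploidy. With membrane as a fixed block 10 spots passed in the diploid, which shared no membrane with the haploid, 40 in the triploid and 36 in the tetraploid. The calls at row 12, column 18, position 1 (adjusted p = 0.27, 0.059 and 0.068) and at row 1, column 7, position 4 (adjusted p = 0.082) were then lost. At the former the log2 differences were then 1.48, 1.40 and 1.57, and at neither spot does the lost call show that membrane carried the change. On the membranes shared with the haploid, 56 of 56 called triploid spots on each of membranes 12 and 13, and 68 of 68 called tetraploid spots on membrane 12, differed in the direction called, but the calls were made from these arrays. Run-on number paired the arrays of haploid and tetraploid, and with it as a block 126 spots passed, 11 higher and 115 lower. The diploid count was 29 without diploid replicate 2. The triploid count was 30 without haploid replicate 3 and 33 without triploid replicate 2. The tetraploid count was 42 without haploid replicate 2, 39 without haploid replicate 3, 38 without tetraploid replicate 2 and 40 without tetraploid replicate 3.

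**Figure D2:**
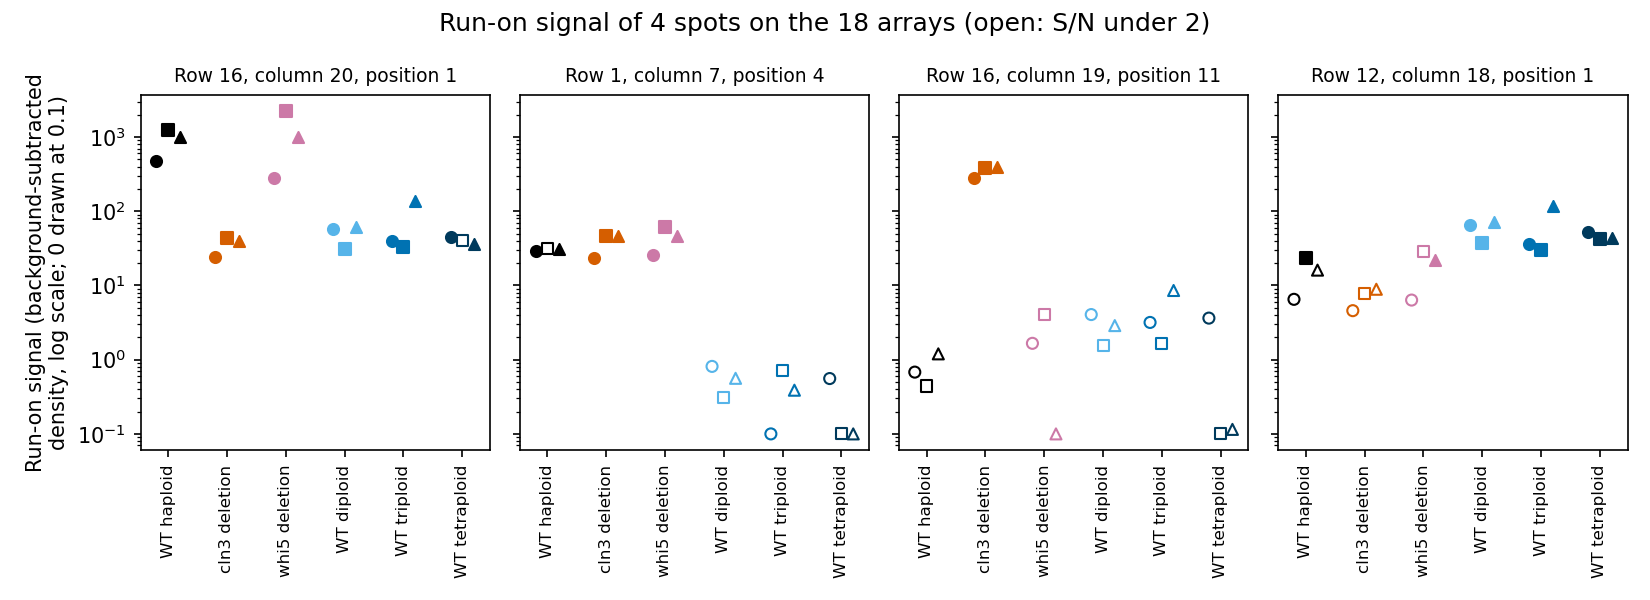
Background-subtracted run-on signal (vertical axis, log scale, with a signal of 0 drawn at 0.1) of 4 spots on each of the 18 arrays, by strain. Each symbol is 1 array, its shape gives the run-on number, and open symbols have an S/N under 2. The spot in row 16, column 20, position 1 is bright in the haploid and the whi5 deletion and dim in the cln3 deletion and the polyploids, row 1, column 7, position 4 is at background in the 3 polyploids, and row 16, column 19, position 11 is bright in the cln3 deletion.

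The 3 polyploids lost signal at shared spots. A set of 37 spots was lower than in the haploid in all 3 and 2 were higher in all 3. Diploid and triploid shared 39 lower spots, diploid and tetraploid 39, and triploid and tetraploid 45, where independent lists would share 0.35, 0.45 and 0.53. Simulated unchanged groups against a common haploid shared 0 on average for each pair. No spot was changed in that simulation, so hardly any call could be shared and the 0 is no test of the overlap. Over 5845 spots with all values, fold changes against the haploid correlated with r = 0.74, 0.84 and 0.85 (Spearman's rho 0.63, 0.77 and 0.78), against 0.50 in the simulation. Their covariance was 0.112, 0.131 and 0.142 against 0.057, 0.056 and 0.057 simulated. The simulated noise was independent between arrays, so these simulated values leave out deviations shared by run-on number or membrane. The 3 haploid arrays could not be split into groups of at least 2. In a pair of contrasts with no run-on array in common, diploid minus whi5 deletion against tetraploid minus haploid, r was 0.52 and rho 0.43 over 5932 spots. With the cln3 deletion in place of the whi5 deletion r was 0.36 and rho 0.32. The 2 sides of each pair still shared membranes and their genomic DNA. Over the spots with a value on every array involved, r was 0.563 and 0.374 for these pairs. Without division by genomic DNA it was 0.616 and 0.411, so these correlations were present without the shared divisor. Leaving it out keeps what the membranes share in the run-on signals, so this does not clear the genomic DNA values as a source. The run-on arrays still shared membranes. With only arrays on membranes that enter 1 side, r was 0.39 for the former pair and -0.001 for the latter, from fewer arrays and with run-on numbers unbalanced, so how much of the resemblance between polyploids is free of shared arrays stays open. These correlations are across spots, which are not independent replicates. The mean of the 3 polyploids differed from the haploid at 86 spots, 7 higher and 79 lower. Quantile normalisation gave 13 higher and 58 lower, and membrane as a fixed block 53 spots. Run-on number as a block gave 185, membrane as a random block 130 and both blocks 347. The count was 57 without haploid replicate 2 and 50 without haploid replicate 3. This combined contrast was chosen after the data were seen.

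Among the polyploids themselves, little difference was detected. Tetraploid against diploid gave 0 of 5936 spots in limma, with 66 spots at an unadjusted p under 0.05 where 297 would be expected by chance. A count so far below that expected by chance can come from p-values that are too large, so it does not show that these strains are alike. The smallest p belonged to row 12, column 24, position 5, with a log2 difference of -2.27 (SE 0.52, adjusted p = 1), and to row 14, column 14, position 15, with 1.18 (SE 0.29, adjusted p = 1). The former passed without tetraploid replicate 1 (log2 difference -3.01, adjusted p = 0.017), the 1 spot called then. A linear trend of log2 ratio on log2 ploidy over the 12 wild-type arrays passed at 71 spots, 9 rising and 62 falling. Without the haploid arrays 0 spots passed, with 84 at an unadjusted p under 0.05, and with a slope per chromosome set in place of log2 ploidy 2 spots passed. With membrane as a fixed block the trend gave 0 spots, as a random block 135, and with run-on number as a block 119. It gave 12, 11 and 6 spots without haploid replicate 1, 2 or 3. Over the 56 spots called in triploid against haploid, diploid and haploid differed by a median of 1.47 log2 units in the direction called. Tetraploid and diploid differed there by a median of 0.12 (95% bootstrap interval over spots 0.05 to 0.17), in the direction called at 41 of 56 spots.

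Whether the difference between the deletions ran parallel to that between tetraploid and diploid, both ordered from the smaller to the larger cell, was asked across spots. The 2 differences share no run-on array, but share 2 membranes with their genomic DNA, and correlated with r = 0.096 and rho 0.15 over 5933 spots. Over the 5867 spots with a value on every array involved r was 0.169, and with only arrays on membranes that enter 1 side it was -0.212, so not even its sign was stable. Other splits of the same arrays gave an absolute r as large in 63 of 100 cases. The value was 0.152 without whi5 deletion replicate 1, 0.019 without whi5 deletion replicate 2, 0.012 without diploid replicate 2 and 0.009 without tetraploid replicate 3. It was 0.25 with uncorrected density, 0.162 without genomic DNA and 0.163 in the upper 75% of signal.

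Over all 6 strains, limma's F test called 145 of 5931 spots. Leaving out 1 array gave between 114 and 157, and membrane as a fixed block 54. In a principal component analysis of the 5845 spots with all values, the first component (21.1% of variance) placed the 6 arrays of run-on 1 at 15.17 or above and the other 12 at -5.26 or below. The second (16.6%) placed the 9 polyploid arrays at -1.71 or above and the 9 haploid and deletion arrays at -5.76 or below. Membranes 14, 15 and 18 each held arrays of only 1 of these sets, so membrane is partly confounded with this separation. Without the 6 arrays of run-on 1 the F test called 120 spots.

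**Figure D3:**
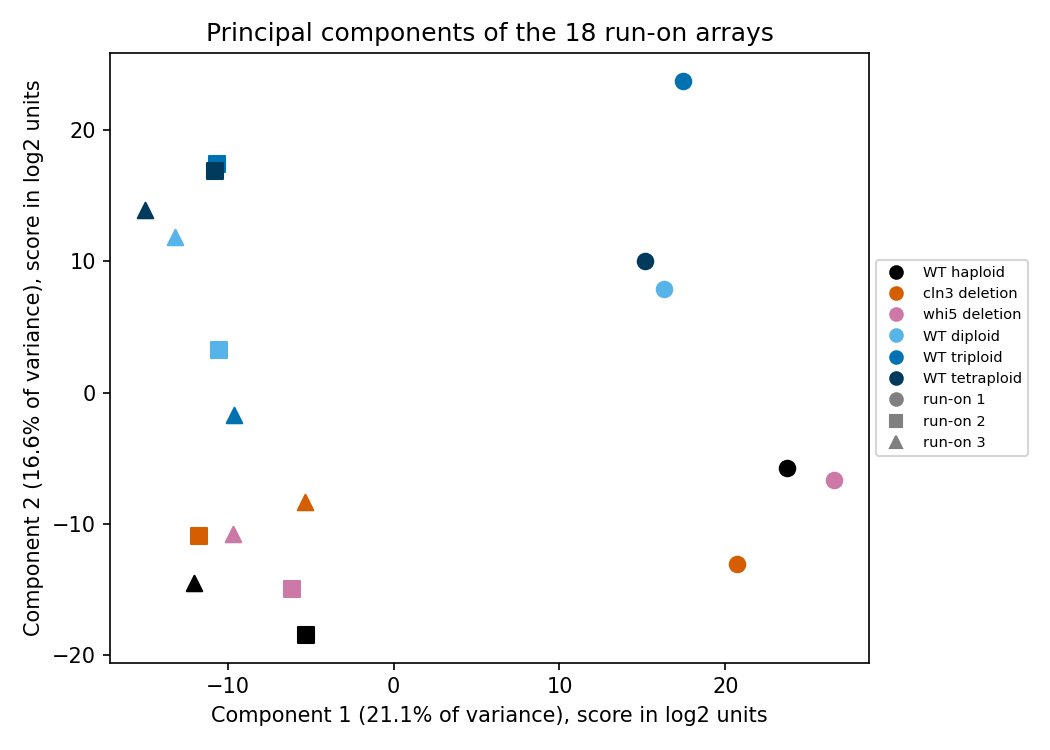
Scores of the 18 run-on arrays on the first principal component (horizontal axis, 21.1% of variance) and the second (vertical axis, 16.6%), in log2 units. Colour gives the strain and symbol shape the run-on number. Run-on 1 arrays of all 6 strains lie to the right, and the 9 polyploid arrays lie above the haploid and deletion arrays.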

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

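The tests of the deletion strains' silent spots were chosen after the spots had been seen, except the test of the detection limit. Of the 207 spots left out of the tests, 5 had an S/N of at least 2 on all 3 run-on arrays of a strain. Separately, 1 spot (row 5, column 3, position 16) was listed at 0 on all 3 cln3 deletion arrays and thus had no test against that strain, though with signals floored it is among the spots of the cln3 deletion and polyploids described under the other observations, while its S/N was 2.65 to 2.73 in the haploid, 2.87 to 3.98 in the whi5 deletion and 2.11 to 2.72 in the diploid. It was 0.71 to 2.12 in the triploid and 1.18 to 3.60 in the tetraploid.

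Each deletion strain had 1 spot that was silent there and called against the haploid, yet present on all 15 other arrays. Both were singled out after their values were seen. By S/N alone the scan gave 1 spot for the cln3 deletion, 2 for the whi5 deletion and 1 for the wild-type haploid, and the second whi5 deletion spot was dropped once it was seen not to pass the test. In the cln3 deletion it was row 14, column 1, position 5, at least 7.8-fold below the haploid. Only 1 cln3 deletion array had a signal above 0 there, so the call rests on that array and its p is not given. In the whi5 deletion the silent spot was row 10, column 16, position 12, at least 7.6-fold below (adjusted p = 2.9e-05 in limma). That test used the 2 whi5 deletion arrays with a signal above 0. The call was lost with membrane as a fixed block (adjusted p = 0.051) and with only the 2 strains in the fit (adjusted p = 0.21), which does not show a smaller change. A failed spot or membrane stays open. Arrays of other strains on the same membranes had an S/N of at least 2.74 at these spots, but the spots had been picked for signal on all 15 other arrays. With signals floored, the lowest of the 15 other arrays lay at least 1.40 log2 units above the highest of the 3, which argues against a place near the detection limit for these 2 spots. They had been kept for passing the test, however, and the other 2 spots found by S/N alone gave -0.15 (haploid) and -0.74 (whi5 deletion). An open reading frame absent from the strain, such as the deleted gene, may be a candidate explanation. With signals floored, 0 spots of the 4 wild types lay at least 1 log2 unit below all other arrays, but without gene names this stays open. The genomic DNA of the cln3 deletion's spot was itself below an S/N of 2 on 2 membranes.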

How the results depend on the processing

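Floored signals, both blocks together, the fit without the 6 run-on 1 arrays, the mean of the polyploids and the correlations from arrays that share no membrane were chosen after the results had been seen. No named spot changed direction. Of 488 values of called named spots under alternatives, 446 kept their call and 42 lost it (17 when an array was left out). Several dim named spots were removed by the filter on the upper 75% of signal. They have no value there and are not counted as lost. Of 42 values of the named spots not called, 41 stayed so and 1 passed. The causes of the changes below were not tested. For counts, run-on number as a replicate block gave 76 spots for cln3 deletion against haploid, 93 for the triploid, 144 between the deletions, 119 for the trend and 185 for the mean of the polyploids. In the comparisons paired by run-on number it gave 10 for the whi5 deletion, 126 for the tetraploid and 58 for the diploid (3 higher, 55 lower), and each spot named there kept its call. Membrane as a fixed block gave 0 for the whi5 deletion, 10 for the diploid, 36 for the tetraploid, 21 between the deletions, 53 for the mean of the polyploids, 0 for the trend and 54 for the F test. As a random block it gave 73 for the cln3 deletion, 114 for the tetraploid, 130 for the mean of the polyploids and 135 for the trend. With only the strains compared in the fit, which leaves fewer arrays, the counts were 21 (cln3 deletion), 0 (whi5 deletion), 24 (diploid), 28 (triploid), 33 (tetraploid) and 35 (between the deletions). With both blocks they were 276 (122 higher, 154 lower), 8 (4 and 4), 82, 430, 292 and 165 in the same order, 347 for the mean of the polyploids, 47 for the trend and 354 for the F test. The whi5 deletion gave 3 without MAD scaling, with quantile normalisation, with uncorrected density and without the run-on 1 arrays, and 2 with signals floored. The trend gave 42 without division by genomic DNA, 47 without the run-on 1 arrays, 0 without the haploid and 2 with a slope per chromosome set. Between the deletions, the upper 75% of signal gave 55.

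Without division by genomic DNA, the overall level differed from the haploid by -0.04 in the cln3 deletion, 0.38 in the whi5 deletion (a change of sign from -0.07), 0.56 in the diploid, 0.53 in the triploid and 0.28 in the tetraploid. The mean of the linear signal turned diploid and tetraploid to -0.11 and -0.13. The fold change correlation was 0.162 without genomic DNA, 0.25 with uncorrected density and 0.163 in the upper 75% of signal. Leaving out each array in turn, counts ranged from 18 to 47 (cln3 deletion), 3 to 4 (whi5 deletion), 29 to 35 (diploid), 30 to 61 (triploid), 38 to 62 (tetraploid), 45 to 77 (between the deletions), 0 to 1 (tetraploid against diploid), 6 to 89 (trend), 114 to 157 (F test) and 50 to 109 (mean of the polyploids). The overall level ranged from -0.45 to 0 (cln3 deletion), -0.41 to 0.28 (whi5 deletion), -0.14 to 0.28 (diploid), -0.01 to 0.69 (triploid) and -0.28 to 0.32 (tetraploid), and the fold change correlation from 0.009 to 0.152. Planned tests of gene lists, of the deleted genes and of marker genes were not run, because the files pair no spot with a gene. Signal over background limits the fold changes of dim spots to bounds.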

Other observations

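The tests of a graded change and of the haploid arrays, of the fold change correlation, the regroupings within run-on numbers and all tests of the spots shared by cln3 deletion and polyploids were chosen after the results had been seen, with the predictions for the regroupings within run-on numbers written before those were run. Beyond single contrasts, the cln3 deletion lay with the polyploids at some spots and alone at others. With signals floored, 26 spots had all 12 cln3 deletion and polyploid arrays on one side of all 6 haploid and whi5 deletion arrays, 25 of them lower. With the whi5 deletion in the place of the cln3 deletion there were 11 such spots, and with the haploid 5. Only the cln3 deletion had spots at least 1 log2 unit above the arrays of all other strains, 12 of them. Among the 84 choices of 3 of the 9 haploid and deletion arrays to stand with the polyploids, 1 gave 26 or more, the cln3 deletion itself, and the highest other gave 21. That one was the 3 arrays of run-on 1, so that structure of the arrays yields almost as many. This test of arrays replaced an exact binomial test across spots (26 against 11, p = 0.02) after those counts were seen, because spots are not independent replicates. A genotype shared by the cln3 deletion and the polyploids, behind these 26 spots, may be a candidate explanation. Mating type would give such classes, as a-specific genes are silent in alpha and a/alpha cells and alpha-specific genes are active in alpha cells alone. The labels give no mating type for these strains, the salt named in one label of the cln3 deletion stays open for spots high in that strain alone, and the spots have no gene names, so these cannot be told apart.

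The loss of signal shared by the polyploids was tested against 3 explanations. At the spots called in triploid against haploid, an evenly graded change with chromosome number is argued against. Tetraploid and diploid differed there by a median of 0.12 log2 units where diploid and haploid differed by 1.47. The spots were chosen with the same haploid arrays, which can enlarge the 1.47 but not the 0.12. The bootstrap interval over spots does not cover the spread between arrays. Haploid wild-type arrays that stand apart on their own are also argued against. At the 86 spots called for the mean of the polyploids, the polyploids differed from the whi5 deletion by a median of 1.17 log2 units in the direction called (95% bootstrap interval 0.97 to 1.31, the same direction at 83 spots), against 1.21 from the haploid. The 86 spots were chosen with the same polyploid arrays, which can enlarge the 1.17 as well. This bootstrap interval over spots does not cover the spread between arrays either. Tested directly, the mean of the polyploids differed from the whi5 deletion at 112 spots, 26 higher and 86 lower. Of these, 61 were also called in that direction against the haploid. Among 100 choices of 3 of those 12 arrays, 2 gave as many, and the highest other gave 157, from the 3 arrays of membrane 18, all polyploid. A defect in one area of the membranes would crowd the called spots into blocks. They formed 13 pairs in the same block, within the 14 that 95% of 1000 random sets of spots did not exceed. The random sets had a median of 9, so the 13 lies close to that limit and some crowding stays open. A step between haploid and polyploid cells, or a difference of strain background between BY4741 and the polyploid strains, may lie behind the pattern (median 1.17 from the whi5 deletion). The design has 1 strain per ploidy and leaves both open.

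Other groupings of the same arrays bear on the counts. For 2 strains there are 10 splits of the 6 arrays, too few for a share under 0.05. The real split gave 43 spots for cln3 deletion against haploid and the highest other 1. The values were 5 and 0 for the whi5 deletion, 44 and 0 for the diploid, 56 and 3 for the triploid, 69 and 1 for the tetraploid, and 94 and 0 between the deletions; in each of these 1 split of 10, the real one, reached the real value. Tetraploid against diploid gave 0 and the highest other 1, so all 10 splits reached it. Where run-on number paired the arrays, the other 3 splits that part all 3 pairs gave 0 spots in each comparison. Of 100 regroupings of the 18 arrays, 1 reached the 145 spots of the F test, the real one, and the highest other gave 60. Among 100 regroupings that kept 1 array of each run-on number in every group it was again the real one alone, with 110 the highest other. For the ploidy trend 2 of 100 reached 71 spots, and for the mean of the polyploids 2 of 100 reached 86, and the highest others gave more than the real grouping. The 201 spots of the former came when 3 of the 4 run-on 1 arrays were put together as haploid, and the 162 of the latter when the 3 arrays of membrane 18 were set against the rest (the next highest gave 3). Both point to a structure by run-on and by membrane. Membrane 18 held an array each of the diploid, triploid and tetraploid and none of the haploid or deletion strains. Membrane was therefore partly confounded with polyploidy, and the real grouping holds part of this structure too. Within run-on numbers, 1 of 100 regroupings reached the trend's 71 spots, the real one, with 66 the highest other. For the mean of the polyploids 3 of 64 reached 86 against the haploid, with 140 the highest other, and 2 of 64 reached 112 against the whi5 deletion, with 146 the highest other. With membrane as a fixed block the trend gave 0 spots and the mean of the polyploids 53, with run-on number as a block 119 and 185, and with both 47 and 347. The counts thus moved both ways with the array structure taken out, and its part in them stays open. The fold change correlation of 0.096 was reached by 63 of 100 pairs of splits, with 0.555 the highest other, so chance is not excluded.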
